A study of Mus musculus with 6 samples.

How the data were processed

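Polyadenylated RNA from 6 cultures of a clonal C2C12 line carrying the MMH transgene was made into libraries with a TruSeq RNA kit, per the labels' protocols, 3 with doxycycline and 3 without. The libraries were pooled with others and sequenced together, per the labels. Nothing in the sources used here ties a replicate number to a shared dish or day. Reads were converted with CASAVA and aligned to mm10 with TopHat2 2.0.12 and Bowtie2 2.2.3, per the submitters' processing notes. The deposited table gave raw counts of reads per gene for 24028 Entrez genes. The read counter, its strand setting, its treatment of reads that map to several places and the annotation release are not given in the sources used here. Overlapping and antisense genes, and copies of repeated families, can therefore share reads in these counts. Of the gene identifiers, 23968 matched the RefSeq table of GRCm38.p6, from which coordinates were taken, and 13 rows had no symbol. mm10 is the same assembly as GRCm38.

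Groups were taken from the treatment label. Counts were analysed as deposited in R 4.3.3. Genes with too few counts were removed with filterByExpr at its defaults, which left 12969 genes, and 5439 genes of the table had no count in any library. Libraries were scaled with TMM factors, on average 1.40 for uninduced and 0.716 for induced libraries. Differences were tested with edgeR 4.0.16 (glmQLFit with robust=TRUE and glmQLFTest, group as the only term, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors are the log2 fold change divided by the square root of F. They can understate the error where a group has few counts. C87499, with 3 uninduced counts, had a standard error of 0.178 on the log2 scale. Its 95% counting interval, described below, ran from 688 to 9769 as a ratio. CPM values were computed on the TMM-scaled library sizes. Gene lists were tested with camera at a preset correlation of 0.01 where 5 or more members were tested, adjusted over 20 lists of 24, with an estimated correlation and fry as alternatives. Members of a list were also adjusted over the list alone. The gene lists, the main tests and the alternatives named below were fixed before the data were examined, whereas several further tests were chosen after results were seen and are marked as such.

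A gene with no count in 1 group was given a lower bound of fold change against a floor of 3 counts over the group's 3 libraries, and with 1 to 3 counts a ratio with an exact 95% binomial counting interval. Intervals and floors cover counting error only. A floor of 3 counts in a single library corresponds to 0.0898 to 0.0983 CPM in uninduced and 0.171 to 0.194 CPM in induced libraries. The biological coefficient of variation was 4.27%. Counts were simulated for these libraries with 200 of 12969 genes changed, all drawn from genes above about 1 CPM, and 12391 tested. The test recovered 84% of changes of 0.5, 98% of 1 and 100% of 2 and of 4 on the log2 scale. It called 10 of 12191 unchanged genes. When only the 100 most abundant genes were changed in a simulation of 12399 tested genes, TMM left 5 unchanged genes called, against 12119 with library size as the only scaling. In both simulations most genes were unchanged, whereas 82.5% of the genes tested in the data were called. They therefore cannot show how the scaling performs when most genes change.

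The genes named were chosen by rule. Among genes past the threshold, not overlapping between groups and with a mean of 1 CPM or more, the 10 largest rises and the 10 largest falls were named, leaving out provisional symbols (2 higher and 1 lower passed over) and taking at most 2 members of a family. To these were added the 5 most abundant genes rising and the 5 falling at least 2-fold, up to 2 rising and 2 falling members of each list, and the Dux family. Genes outside this rule are described as chosen after their values were seen. The result of 1 gene that the rule selects is not reported here. Repeated families were also summed. The alternatives tried were DESeq2 1.42.0 with its own size factors and Wald test, limma-voom (limma 3.58.1), RLE, upper-quartile and library-size-only scaling, other count filters, robust=FALSE, a replicate block, each library left out, repeated families removed, an adjusted p of 0.01, a log2 fold change of 2 and a glmTreat test against 1.5-fold. Genes such as Duxbl1, Zscan4e and Cphx1, cells with doxycycline and no transgene, and the human dataset to which the series was to be compared were not analysed here.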

Results

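Messenger RNA was profiled in a clonal line of C2C12 cells, an immortalised mouse myoblast line, that carries a doxycycline-inducible transgene called MMH. The transgene joins the amino-terminal part of mouse Dux, including its homeodomains, to the part of human DUX4 that follows its homeodomains. Dux and DUX4 are transcription factors normally active at the onset of zygotic transcription, and misexpressed DUX4 is linked to facioscapulohumeral muscular dystrophy. Separate cultures gave 3 libraries with 2 µg/ml doxycycline (induced) and 3 libraries without it (uninduced). The series description gives 18 h of induction and the sample protocol gives 36 h, so the duration behind every value is uncertain between these figures. Cells with doxycycline and without the transgene were not analysed here, so every difference is that of drug and transgene together. The libraries held 21.5 to 24.5 M counts each, with a mean of 22.6 ± 1.17 M (SD, n = 3) in uninduced and 23.5 ± 1.72 M (SD, n = 3) in induced cells. Counts were found for 15594 ± 65.6 genes per uninduced library and 16361 ± 74.0 genes per induced library (SD, n = 3). Replicates of a group correlated across genes at r = 0.993 to 0.997 in log2 CPM, against 0.837 to 0.844 between groups. Each library was counted as a separate sample because the series description gives separate cultures. Replicate pairs differed beyond counting noise, with a chi-square statistic of 2.40 to 6.77 times its degrees of freedom, which argues against a library entered more than once but does not by itself show separate cultures.

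The comparison asked which transcripts change when the chimeric factor is switched on in mouse myoblasts. Transcripts of cleavage-stage embryos rose strongly, including the Zscan4, Pramef, Usp17l, Tcstv and Tdpoz families. The Zscan4 family came to take a large part of the counts of induced libraries, unlike the Usp17l, Tcstv and Tdpoz families. Most tested transcripts of cholesterol synthesis fell, Idi1 among them. Most of those of myoblast identity and extracellular matrix fell as well, such as Myod1 and Col1a2, but these list calls were lost with an estimated correlation (adjusted p = 0.22 and adjusted p = 0.289 with an estimated correlation). The 5 Zscan4 genes, which encode zinc-finger proteins of the late 2-cell embryo, together took 17.8% ± 0.233 of the counts of induced libraries and 0.133% ± 0.00301 of those of uninduced libraries (SD, n = 3 each). The 20 most abundant genes of the induced libraries held 42.8% ± 0.291 of induced counts and 2.96% ± 0.0132 of uninduced counts (SD, n = 3). These are shares of counts, and a read from near-identical copies may have been counted at more than 1 gene: Gm10697 and Tdpoz5 had identical counts in all 6 libraries, and Zscan4c and Zscan4f nearly equal ones.

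**Figure D1:**
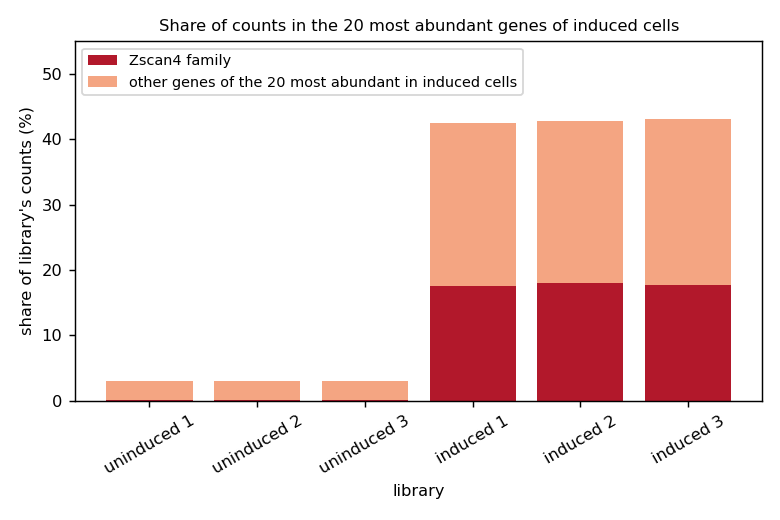
Bars show, for each of the 6 libraries, the percentage of its counts that fell in the 20 genes most abundant in induced cells, with the Zscan4 family in the darker part. The 3 induced libraries lie at 42.5% to 43.1% and the 3 uninduced libraries at 2.95% to 2.98%.

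Of 12969 genes tested with edgeR's quasi-likelihood test, 10698 passed a Benjamini-Hochberg adjusted p of 0.05, 5351 of them higher and 5347 lower in induced cells. A change of at least 2-fold was found for 3981 genes, 2333 higher and 1648 lower, but the majority turned with upper-quartile scaling (2032 higher and 2122 lower) and with library size as the only scaling (1087 higher and 6336 lower). Large changes were mostly increases by edgeR's fitted values, since 440 genes rose and 6 fell at least 16-fold, and 249 rose and 2 fell at least 64-fold. No count was found in any uninduced library for 55 of the genes that rose, and all 55 are among the 249. Their fitted folds are not bounds, as Sox2 was fitted at 251-fold but had a lower bound of 40.7-fold. The groups did not overlap in CPM for 10780 genes, or 83.1% of those tested, against 10% by chance with 3 libraries per group. Directions are relative to the middle of all tested genes, as no external RNA standard is recorded in the sources used here. With library size as the only scaling, where the median of all tested genes moved to -0.97 on the log2 scale, 1977 genes were higher and 9949 lower.

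Among named genes expressed at 1 CPM or more on average, the oocyte gene Oog4 had no uninduced count and reached 43.3 ± 3.74 CPM in induced cells (SD, n = 3), which was at least 1364-fold higher. The non-coding transcript AU019990 was at least 520-fold higher, Pramel4 at least 402-fold and the homeobox gene Obox5 at least 307-fold, each against a floor of 3 counts over the 3 uninduced libraries. Pramel5 and A2m had 2 uninduced counts each and ratios of 2391 (95% counting interval 661 to 19757) and 1781 (492 to 14717). C87499, with 3 uninduced counts, had a ratio of 2014 (688 to 9769). Pramef25, on chromosome 4 at 143948183 to 143951016 of GRCm38, rose from 14.3 ± 0.883 to 17533 ± 248 CPM (SD, n = 3), a log2 fold change of 10.26 ± 0.06 (SE, edgeR adjusted p = 6.9e-33). Pramef6 rose by 10.69 ± 0.07 and BC080695 by 10.47 ± 0.07 on the log2 scale. Single members of these repeated families are uncertain because copies can share reads.

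Every one of the 35 tested cleavage-stage genes rose, also 35 adjusted over the list alone, with a median log2 fold change of 8.01 (camera adjusted p = 1.0e-205, and adjusted p = 0.000985 with an estimated correlation). Zscan4f, on chromosome 7 at 11397915 to 11402318 of GRCm38, rose from 282 ± 5.58 to 70708 ± 1086 CPM (SD, n = 3), a log2 fold change of 7.97 ± 0.05 (SE). Zscan4c rose by 7.93 ± 0.05. Summed over members, so that sharing between copies within a family matters less for the fold, the Zscan4 family rose 261-fold. Its sum went from 954 ± 19.4 to 248581 ± 2852 CPM (SD, n = 3). Summed CPM values may hold a shared read more than 1 time. The summed Usp17l deubiquitinase family rose 91.7-fold, the Tdpoz family 248-fold, the Pramef family 457-fold and the Tcstv family 797-fold. The Trim43 family, with 1 of 3 members tested, rose 5.45-fold from 0.449 ± 0.226 CPM (SD, n = 3), an imprecise fold with so few uninduced counts. The Obox family rose from 0.0725 ± 0.0441 to 66.4 ± 4.07 CPM (SD, n = 3), with too few uninduced counts for a precise fold. With library size as the only scaling all 7 family sums rose less, such as Zscan4 by 7.06 in place of 8.03 on the log2 scale. The uninduced libraries had measurable background for most of these families, such as 85.1 ± 2.96 CPM for Usp17l and 1.63 ± 0.0639 CPM for Tdpoz (SD, n = 3). Counts at the Dux row were 1, 3 and 0 in uninduced and 252, 216 and 220 in induced libraries, a log2 fold change of 8.17 ± 0.26 (SE, edgeR adjusted p = 6.4e-19). That SE understates the counting error with so few uninduced counts. The transgene's codons were altered, so counts at the Dux row need not come from it. Duxbl3, a Dux-like homeobox gene, rose by 4.15 ± 0.05 on the log2 scale.

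Of 32 mouse counterparts of genes induced by human DUX4 that were in the counts, 21 had enough counts to be tested. A counterpart silent in uninduced cells could enter only through its induced counts. Among these 21 genes, 20 were higher and 1 lower (20 and 1 adjusted over the list alone). Their median log2 fold change was 7.79 (camera adjusted p = 1.2e-107, and adjusted p = 0.000985 with an estimated correlation), and the list shares all its Zscan4 and Usp17l members, with Pramef6 and Pramef25 but not Pramef17 or Pramef8, with the cleavage-stage list. Rfpl4b rose by 9.78 and the histone demethylase gene Kdm4d by 7.70 on the log2 scale, both chosen after their values were seen. The member that fell was Usp29, at -2.07 ± 0.15 (SE). Of 20 listed pluripotency factors 10 had enough counts to be tested, and a factor silent in uninduced cells could enter only through its induced counts. These 10 were all higher (10 adjusted over the list alone), with a median log2 fold change of 2.54, which stayed at 2.54 with Sox2 set to its bound. The camera adjusted p was 0.0113, but the adjusted p was 0.468 with an estimated correlation. Sox2 had no uninduced count and 1.29 ± 0.456 CPM in induced cells (SD, n = 3), at least 40.7-fold higher, and Dppa2 rose by 5.27 ± 0.18 to 12.8 ± 0.932 CPM. Of 28 listed germline genes only 7 were tested, and these went both ways. Of the 7, 2 were higher, 4 lower and 1 not called (2 and 4 adjusted over the list alone, camera adjusted p = 0.717). Tex19.1 rose by 2.81 ± 0.36 and Sycp2, a synaptonemal complex gene, fell by 2.30 ± 0.63 on the log2 scale. Piwil2, the other that rose, was at 0.14 with library size as the only scaling (edgeR adjusted p = 0.693). Rhox5, called lower, was not called with the DESeq2 Wald test (adjusted p = 0.155).

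**Figure D2:**
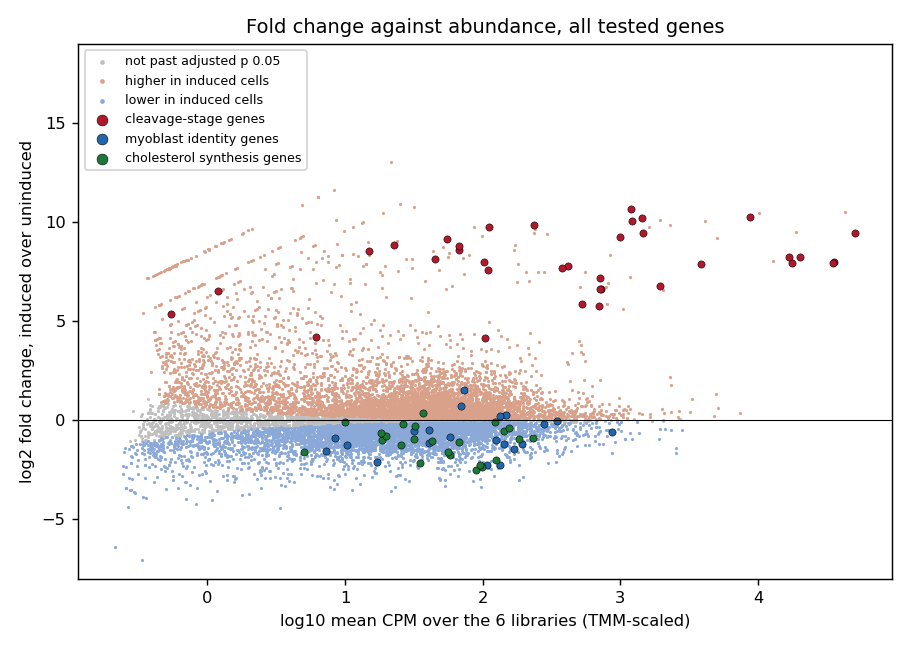
Each point is 1 of the 12969 tested genes, with the log10 of its mean CPM on the x axis and its log2 fold change, induced over uninduced, on the y axis. Points of the cleavage-stage list lie between 4.15 and 10.69, while those of the cholesterol synthesis list have a median of -0.97, and fitted values of genes with no uninduced count are not bounds.

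Transcripts of myoblast identity fell, with 16 of 21 tested members lower, 4 higher and 1 not called (16 and 4 adjusted over the list alone). The median log2 fold change was -0.87 (camera adjusted p = 0.0003, and adjusted p = 0.22 with an estimated correlation). Myod1, the master regulator of the myogenic lineage, fell from 178 ± 4.08 to 37.1 ± 0.896 CPM (SD, n = 3), a log2 fold change of -2.26 ± 0.05 (SE, edgeR adjusted p = 1.2e-22). Cdh15, which encodes M-cadherin, fell by 2.28 ± 0.05, whereas the homeobox gene Six4 rose by 1.53 ± 0.05 on the log2 scale. Myotube differentiation genes were lower in 23 of 35 cases, higher in 4 and not called in 8 (23 and 4 adjusted over the list alone), with a median of -0.28. That list's camera adjusted p was 0.0384, rising to 0.0598 without induced replicate 1, and the adjusted p was 0.772 with an estimated correlation. Myog, the regulator of terminal differentiation, fell by 1.38 ± 0.05 on the log2 scale. Myh8, a perinatal myosin heavy chain gene, rose by 1.04 ± 0.09 but by 0.07 with library size as the only scaling (edgeR adjusted p = 0.444).

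Extracellular matrix transcripts fell in 28 of 33 tested cases, rose in 4 and were not called in 1 (28 and 4 adjusted over the list alone). The median log2 fold change was -0.80 (camera adjusted p = 2.8e-07, and adjusted p = 0.289 with an estimated correlation). Col1a2, a type I collagen chain, fell from 115 ± 6.31 to 16.5 ± 1.78 CPM (SD, n = 3), a log2 fold change of -2.80 ± 0.07 (SE), and Thbs2 was at -2.90 ± 0.23. The collagen-crosslinking enzyme Loxl2 went the other way, from 3.10 ± 0.562 to 69.0 ± 8.31 CPM, a log2 fold change of 4.48 ± 0.11 (SE). The laminin gene Lama4 rose by 2.00 ± 0.13.

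Cholesterol synthesis genes formed the most uniformly lowered of the metabolic lists, with 21 of 24 lower, 1 higher and 2 not called (21 and 1 adjusted over the list alone). The median log2 fold change was -0.97 (camera adjusted p = 3.9e-08), and the adjusted p was 0.0197 with an estimated correlation. Idi1, an enzyme of isoprenoid synthesis, fell from 166 ± 4.15 to 32.3 ± 0.365 CPM (SD, n = 3), a log2 fold change of -2.36 ± 0.05 (SE, edgeR adjusted p = 7.6e-23). Mvd was the member that rose, at 0.39 ± 0.06, but it was at -0.57 with library size as the only scaling.

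Target genes of p53 were mostly higher, 14 of 21 against 4 lower and 3 not called (14 and 4 adjusted over the list alone), with a median log2 fold change of 0.87 that became -0.10 with library size as the only scaling. The camera adjusted p was 0.000358, and the adjusted p was 0.0661 with an estimated correlation. Pmaip1, which encodes the pro-apoptotic protein Noxa, rose by 3.64 ± 0.05 and Sesn2 by 3.01 ± 0.05, while Rrm2b fell by 1.17 ± 0.10 on the log2 scale. Cdkn1a, the p53-inducible cell cycle inhibitor, named after its value was seen, was at 0.04 (edgeR adjusted p = 0.358). Genes of the integrated stress and unfolded protein responses were higher in 17 of 27 cases and lower in 8 (18 and 8 adjusted over the list alone), with a median of 0.44 that became -0.52 with library size as the only scaling. The camera adjusted p was 0.0229, and the adjusted p was 0.468 with an estimated correlation, 0.384 with library size alone and 0.0711 without genes held by several lists. Atf3, a stress-induced transcription factor, rose from 3.56 ± 0.134 to 79.4 ± 3.30 CPM (SD, n = 3), whereas the endoplasmic reticulum chaperone Hsp90b1 fell by 0.48 ± 0.04 on the log2 scale.

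G1/S and replication genes were lower in 17 of 28 cases and higher in 7 (17 and 7 adjusted over the list alone), with a median of -0.29 and a camera adjusted p of 0.0917, or 0.00342 with library size as the only scaling and 0.0103 without the low-count filter, but the adjusted p was 0.468 with an estimated correlation. Mcm6, a subunit of the replicative helicase, fell by 1.64 ± 0.05 on the log2 scale, while Uhrf1 rose by 0.86 ± 0.04 and Slbp by 0.74 ± 0.05. With library size alone these 2 risers were at -0.10 and -0.23. For G2/M genes 13 of 24 were higher and 8 lower (13 and 8 adjusted over the list alone). Their median of 0.13, which became -0.84 with library size alone and -0.02 with upper-quartile scaling, was opposite in sign to the camera direction (adjusted p = 0.993). Kif11, a mitotic kinesin, fell by 1.18 ± 0.06 and Cenpe, another kinesin, rose by 1.32 ± 0.05. Nuclear oxidative phosphorylation genes were lower in 21 of 31 cases and higher in 3 (21 and 3 adjusted over the list alone), with a median of -0.24. Their camera adjusted p was 0.0632, and it was 0.034 without uninduced replicate 1, 0.0468 without induced replicate 3, 0.000287 with library size as the only scaling and 0.000553 without the low-count filter, but the adjusted p was 0.772 with an estimated correlation. Cytosolic ribosomal protein genes were higher in 34 of 44 cases and lower in 3 (34 and 3 adjusted over the list alone), with a median of 0.23 that became -0.73 with library size alone (camera adjusted p = 0.422). Glycolytic enzymes were higher in 9 of 16 cases and lower in 3 (9 and 3 adjusted over the list alone), with a median of 0.12 that became -0.85 with library size alone and -0.03 with upper-quartile scaling (camera adjusted p = 0.422).

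Of 28 listed interferon-stimulated genes 17 were tested, with 11 higher and 3 lower (11 and 3 adjusted over the list alone). Their median was 0.85 (camera adjusted p = 0.611), and it became -0.11 with library size alone. Irf7 rose by 3.56 ± 0.15 and Ifit2 fell by 1.57 ± 0.12 on the log2 scale. Nonsense-mediated decay factors showed 7 higher and 5 lower of 16 (7 and 5 adjusted over the list alone), with a median of 0.01 and a camera adjusted p of 0.991 in the downward direction. With library size alone 1 was higher and 15 lower (median -0.96), and with upper-quartile scaling 6 were higher and 8 lower (median -0.14). Smg8 rose by 1.25 ± 0.06 and Magohb fell by 1.01 ± 0.11 on the log2 scale. Markers of other cell types were sparse. All 5 tested osteoblast markers were lower (5 adjusted over the list alone), including Sp7 at -2.13 ± 0.25, with a median of -1.06 and a camera adjusted p of 0.114. Neuronal markers had 3 of 5 lower and 1 higher (4 and 1 adjusted over the list alone, camera adjusted p = 0.467). Endothelial markers had 2 of 5 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.991), with Pecam1 at 0.793 ± 0.118 CPM in induced cells. The 2 lower calls, Flt1 and Eng, were lost with the DESeq2 Wald test (adjusted p = 0.0583 and 0.0713). Too few members were tested for camera among adipocyte markers (2 higher and 2 lower of 4, with Fabp4 up by 3.91 ± 0.20), macrophage and leukocyte markers (1 higher of 2) and epithelial markers (0 called of 2 by edgeR, DESeq2 or limma-voom). Mitochondrially encoded transcripts were not analysed here.

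**Figure D3:**
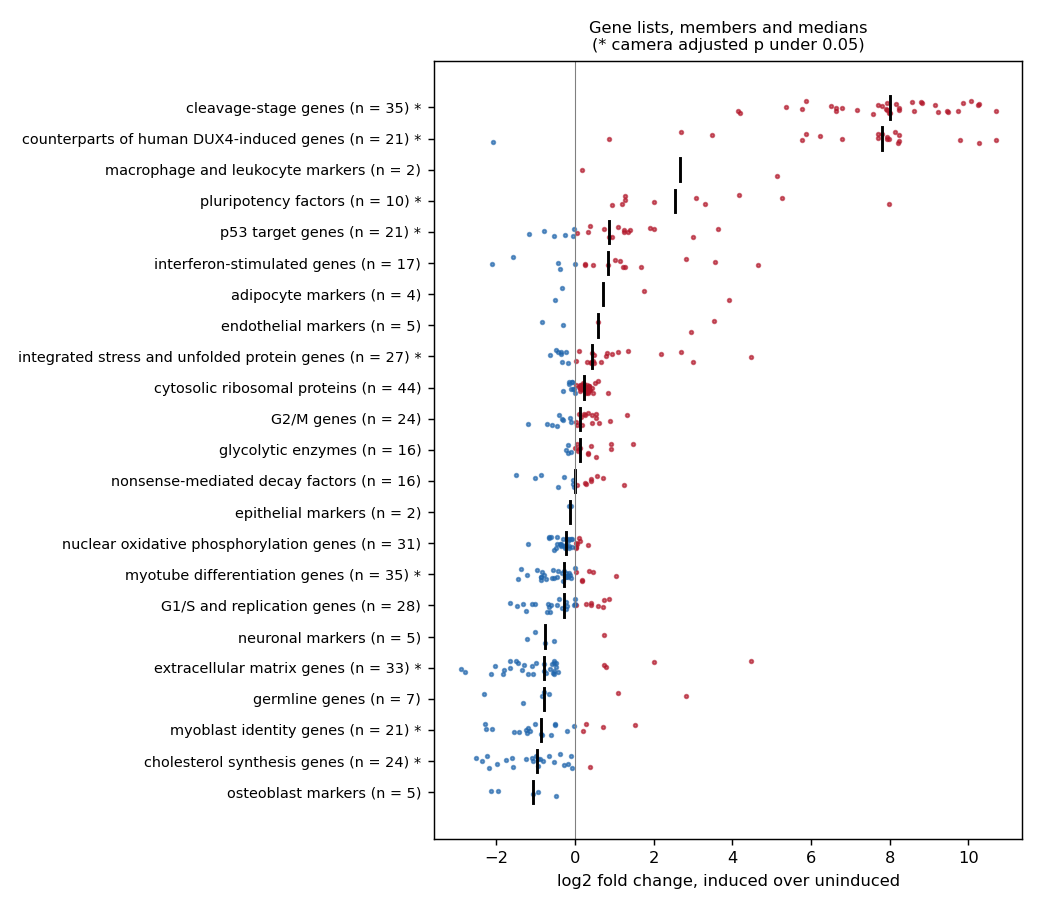
Dots show the log2 fold change, induced over uninduced, of each tested member of the gene lists, red above 0 and blue below, with a random vertical offset, and vertical bars show list medians. The cleavage-stage list has a median of 8.01 and the cholesterol synthesis list a median of -0.97, and asterisks mark the 9 of 20 lists past a camera adjusted p of 0.05.

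The largest falls among named genes included Rab7b, a small GTPase of the endolysosomal system, at -4.42 ± 0.26, and Npas4, an activity-dependent transcription factor, at -4.05 ± 0.44 on the log2 scale (SE). Htra3 followed at -3.78 ± 0.30, Wnt10a at -3.71 ± 0.29 and Lrrc17 at -3.55 ± 0.10. Over the induced libraries Npas4 had 6 counts, Htra3 12, Wnt10a 14 and Rab7b 15, so the SEs of these genes understate the counting error. Pdgfrb, the platelet-derived growth factor receptor beta, was the most abundant of these 10 genes and fell from 177 ± 6.48 to 17.2 ± 1.37 CPM (SD, n = 3), a log2 fold change of -3.37 ± 0.06 (SE, edgeR adjusted p = 2.7e-24). The others were Fam129c at -3.55, G0s2 at -3.50, Daam2 at -3.49 and Kbtbd11 at -3.36. The most abundant genes that fell at least 2-fold were the cytoskeletal genes Actg1 at -1.38 ± 0.04 and Tpm1 at -1.64 ± 0.04, the imprinted non-coding RNA H19 at -1.66 ± 0.04, Thbs1 at -1.09 ± 0.04 and S100a4 at -1.20 ± 0.05. Hspa8, a constitutive HSP70 chaperone, was also among the 5 most abundant named genes that rose at least 2-fold, from 2838 ± 62.0 to 7037 ± 25.3 CPM (SD, n = 3).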

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

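Every alternative here was chosen before the result was seen. Leaving out each library gave 10362 to 10691 changed genes, 3980 to 4123 at 2-fold and 8 to 10 lists. Library size as the only scaling gave 7423 genes at 2-fold, since it sets the median of all genes at -0.97, and a log2 fold change of 2 gave 1326. For lists, the estimated correlation called 3 and fry, which does not compare a list with other genes, called 19. Over 103 named genes, 1207 of 1236 values kept their direction and side of the threshold. Under library size alone 13 named genes reversed: Mef2d (-0.25), Klhl41 (-0.50), Uhrf1 (-0.10), Slbp (-0.23), Ccnf (-0.0754), Rbm8a (-0.26), Pfkl (-0.0470), Atp5b (-0.63), Uqcrfs1 (-0.83), Rps20 (-0.13), Rplp0 (-0.38), Mvd (-0.57) and Tubb3 (-0.21 on the log2 scale). Uqcrfs1 was also at -0.0123 with upper-quartile factors. The DESeq2 Wald test lost the calls of 4 named genes: Rhox5 (adjusted p = 0.155), Uqcrfs1 (0.0549), Flt1 (0.0583) and Eng (0.0713). Among calls lost when a library was left out, Rhox5 was not called without uninduced replicate 2 (adjusted p = 0.117) and without induced replicate 1 (0.17), and Uqcrfs1 without uninduced replicate 1 (0.073) and without induced replicate 3 (0.0724). With replicate number as a block, 10813 genes changed, 3979 at 2-fold, and 10 lists, adding oxidative phosphorylation (adjusted p = 0.0499). Libraries with the same number had deviation correlations of 0.06, 0.02 and 0.03, each the highest for its library among the other group, a hint from the data and not the design. Most 2-fold changes of genes above about 1 CPM were detected on simulated counts in which few genes changed, but genes near the floor stay uncertain.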

Other observations

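Tests of S phase, of a constant background share, of doxycycline alone and of the removal of abundant genes were chosen only after the result was seen, as were the symbol groups, the histone classes and the chromosome positions. Genes were also grouped by the leading letters of their symbols, and 230 groups of at least 8 tested genes were compared with camera. Of these, 10 passed an adjusted p of 0.05, 8 higher and 2 lower, and 0 passed with an estimated correlation. The lowest adjusted p belonged to Zscan genes, which include the Zscan4 family (8.3e-28 by camera, adjusted p = 0.21 with an estimated correlation), and 3 of the 10 groups are described here. Histone genes had 52 of 56 tested genes higher, 0 lower by edgeR and a median log2 fold change of 2.25, or 1.29 with library size as the only scaling (camera adjusted p = 1.2e-11, adjusted p = 1.00 with an estimated correlation). All tested H2A, H2B, H3 and H4 genes rose. Summed H3 genes went from 47.0 ± 1.81 to 379 ± 61.3 CPM and summed H4 genes from 56.4 ± 2.56 to 411 ± 58.6 CPM (SD, n = 3), while 1 of 5 H1 genes rose and the summed H1 genes changed 1.14-fold. The difference between classes was not tested. Core histone messages normally end in a stem-loop and carry no poly(A) tail.

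Heat shock genes of the Hspa group were higher in 8 of 13 cases and lower in 2 (camera adjusted p = 0.000376, adjusted p = 1.00 with an estimated correlation). The inducible genes Hspa1a and Hspa1b, chosen after their values were seen, rose by 5.87 and 5.60 on the log2 scale. All 8 tested septin genes were lower, with a median log2 fold change of -0.78 (camera adjusted p = 0.0129, adjusted p = 1.00 with an estimated correlation). By fitted values, which are not bounds for genes with no uninduced count, 248 genes with a position rose at least 64-fold. Of these, 78 lay in 12 groups of 4 or more, each separated from the next such gene by at most 500 kb. Several groups hold copies of a repeated family, which can share reads and so pass the bound together. Gm10697 and Tdpoz5, with identical counts, lie in the same group. The largest group held 14 genes on chromosome 4 between 143437164 and 144364419 of GRCm38, including Oog4, Pramef6 and Pramel5. Chromosome 4 held 37 of its 853 tested genes in this class, an odds ratio of 2.55 (Fisher's exact test, two-sided, adjusted p = 6.1e-05 over 20 chromosomes). Chromosome 5 held 29 of 810 (adjusted p = 0.0124) and chromosome 7 held 31 of 983 (adjusted p = 0.0348) by the same exact test, although genes of a tandem family are not independent.

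More cells in S phase would raise replication genes together with histones. The G1/S and replication list was split, with 7 of 28 genes higher, Uhrf1 and Slbp among them, and 17 lower. Its median log2 fold change was -0.29, so the list as a whole did not rise with the histones. A less selective capture of polyadenylated RNA may still account for part of the histone rise. Of the RNAs without a poly(A) tail, 5 were tested, with a median of 0.42, and they went both ways: Rpph1 rose by 4.82 and Rmrp by 1.97 on the log2 scale, while Snord88a was at -0.67 (edgeR adjusted p = 0.0287). That median lay below 0.5, the bound set beforehand for excluding capture, but the quartiles of -0.67 and 1.97 reached past it. The condition on the quartiles was added after this median was seen, and with 5 weakly counted RNAs capture and a change in histone message processing cannot be told apart.

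Cleavage-stage transcripts in uninduced cells might be reads or cells carried over from the induced state, which would give each gene the same ratio of uninduced to induced level. Over 29 genes of the list at 100 CPM or more in induced libraries, the 90th percentile of that ratio was 12.6 times the 10th, from 0.0916% to 1.15%, far beyond counting error. Pramef6 had the lowest ratio, 0.0602% (95% counting interval 0.0505% to 0.0711%), and Duxbl3 the highest, 5.65%. A constant share could therefore account for at most 18.5% of the Zscan4 counts of uninduced libraries, whose ratio was 0.384%. Low transgene activity without doxycycline is a hypothesis that stays open, as no line without the transgene was analysed here.

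Lower cholesterol synthesis transcripts could reflect transcript length or GC content. After removal of the trend on both, which explained 2.01% of the variance of log2 fold changes, the list median was -1.05 (camera adjusted p = 9.6e-08), against -0.97 before. Doxycycline itself stays open as a cause, because 0 groups with doxycycline and no transgene were analysed here, so drug and transgene cannot be told apart for this list. The same limit of the design holds for every other difference between induced and uninduced cells.

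The hypothesis of transcription running past the ends of strongly induced genes was tested on genes within 50 kb of them. Strongly induced here means a rise of at least 64-fold by fitted values. Left out were repeated families, members of the same family and genes that themselves rose at least 64-fold. The 47 downstream neighbours had a median log2 fold change of 0.04 and the 44 upstream neighbours 0.21, a difference of -0.16 (permutation test, two-sided, p = 0.495). Because 19 strongly induced genes near another of a different family were left out by that rule, the test cannot decide on such transcription, which stays open. With the 100 most abundant genes of the induced libraries removed, which held 52.7% of induced counts, 99.6% of the 10605 remaining called genes kept their call and direction. In the simulation with only the 100 most abundant genes changed, TMM left unchanged genes at a median log2 fold change of -0.000606. The removal was thus unlikely to move the factors and does not test whether the scaling sets the directions. Regrouping the 6 libraries gave 10 splits, too few for a share under 0.05. The real split called 10698 genes and 3981 genes at 2-fold and was the 1 split to reach either count, as the highest of the other splits called 0 for both by edgeR. For gene lists the real split called 9, while 6 of the 10 splits, the real one included, reached as many and the highest other called 12. Every other split mixed induced and uninduced libraries on both sides. The induction difference thus widened the spread within its sides and in part remained between them. The other splits therefore do not show what chance alone would give, for genes or for lists. The number of lists called with the preset correlation did not set the real grouping apart from these mixed splits.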
